A study of Rattus norvegicus with 8 samples.

How the data were processed

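Lung tissue of rats (Rattus norvegicus) was profiled by RNA sequencing in 2 groups of 4 libraries: MCT, from rats given monocrotaline to model pulmonary hypertension, and control. Monocrotaline is a plant alkaloid that injures the pulmonary vessels of rats. The labels give no dose, no time after treatment and no statement that the libraries of a group came from separate animals, so the p-values measure the spread between these libraries, part of which may be technical.

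The authors trimmed reads with cutadapt 1.9, aligned them with HISAT2 2.0.4, assembled and quantified with StringTie 1.3.4d and named edgeR, against the rat build Rnor_6.0, per the submitters' processing notes, which give no order or settings for these tools. The deposited table holds 32623 annotated genes, each with a position, a biotype, an estimated count and an FPKM value (fragments scaled to transcript length and sequencing depth) in each of the 8 libraries, per the file headers. The deposited estimated counts are whole numbers. Their low values pile up at 4, 8, 12 and 15, so 1 read pair was worth about 3.69 units, a spacing found by a periodogram of the values. The totals of 39.8 to 66.6 M units per library therefore stand for about 10.8 to 18 M read pairs, and the count tests treat the spread between libraries, not the units, as the error. All value columns matched a library.

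The design written before the data were examined took limma on log2(FPKM + 0.5) as the test unless the table also held whole-number counts, in which case edgeR's quasi-likelihood test took its place. The table did hold such counts, and edgeR was used on them after rounding, which changed no value. Genes were kept by edgeR's filterByExpr (minimum count 10), which left 16715 genes. Libraries were scaled by TMM, dispersions were estimated robustly, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. Log2 fold changes are MCT minus control with their standard errors, and FPKM values are given as mean ± SD over 4 libraries. The versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.

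Before the data were examined, 33 gene lists of pathways and cell types were also fixed: extracellular matrix, basement membrane, smooth muscle, pan-endothelial, capillary, BMP and TGF-beta, heritable pulmonary arterial hypertension, vasoactive pathways, alveolar type 1, alveolar type 2, transitional, club, ciliated, macrophage, mast, B, T and NK, neutrophil, cytokine, interferon, complement, MHC class II, cell cycle, p53, glycolysis, oxidative phosphorylation, cardiac, skeletal muscle, adipocyte, mesothelial, red blood cell, circadian and immediate early. Members were counted as higher, lower or not past the threshold over all genes tested, and again adjusted over the list alone. Each list was tested against all other genes with camera in limma on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the lists, and again with the correlation estimated per list. Named genes were the 10 largest rises and the 10 largest falls among called genes with a gene symbol, mean FPKM of at least 2 in the higher group and no overlap between the groups, leaving out MHC, immunoglobulin and T cell receptor symbols. The 2 called members of each list with the smallest p were named too, or the tested member with the highest mean FPKM where none was called. This gave 75 genes. Other genes are given as examples of a list.

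The edgeR step was tested on 10 simulated data sets made from the real means, library sizes and dispersions of MCT against control, with 200 genes changed in each and 16389 to 16419 genes tested. It recovered 22.5% of the genes changed 1.5-fold, 68.3% of those changed 2-fold and 94.8% of those changed 4-fold. On average 6.1% of its calls were unchanged genes, with a range of 0.935% to 10.6%. The changed genes were not drawn from those of lowest mean expression, so the recovery of such genes was not measured.

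Alternatives fixed in advance were limma on log2(FPKM + 0.5), pseudocounts of 0.1 and 1, no filter, FPKM of at least 1 in 4 libraries, DESeq2 size factors, median-of-ratios and quantile scaling, array weights, the replicate number as a block, each library left out, an absolute log2 fold change of at least 1, and DESeq2. Added after seeing the data were a ciliated cell score as a covariate, control 1 and MCT 1 both left out, counts divided by 3.69, and removal of each library's trend with gene length. No pair of libraries in a group was a duplicate: the chi-square per gene between libraries of a group was at least 18. The counting of reads shared between paralogs and between strands is not given in the sources used here.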

Results

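Gene expression was measured by RNA sequencing of rat lung in 4 libraries from animals given monocrotaline (MCT) and 4 control libraries. The labels present MCT as a model of pulmonary hypertension from which targets with large differences were to be chosen. The deposited counts stood for about 10.8 to 14.7 M read pairs in the control libraries and 11.2 to 18 M in the MCT libraries.

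The groups lay apart on the first principal component of log2 CPM (34% of the variance). Correlations across genes were 0.937 to 0.958 within a group and 0.92 to 0.936 between groups. The libraries MCT 1 and control 1 stood apart on the second component (15.3%), at 77.2 and 24.8, against -36.9 to -4.5 for the others. These 2 libraries also had the highest ciliated cell scores, a mean log2 CPM of 5.00 in MCT 1 and 4.33 in control 1 against 2.48 to 3.88 in the others. MCT 1 had the highest cardiac myocyte score, 2.73 against 1.23 to 1.75. Mitochondrial genes took 3.24% to 4.59% of the counts in the MCT libraries and 2.86% to 3.5% in the control libraries.

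**Figure D1:**
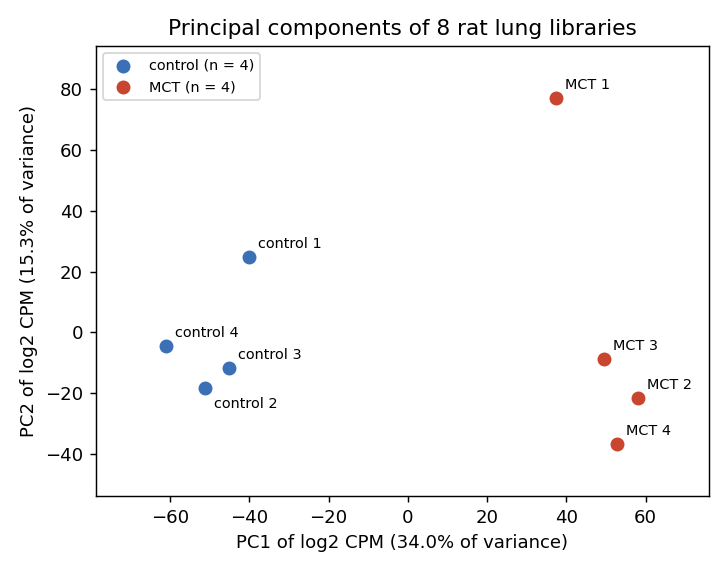
Principal components of log2 CPM for the 8 libraries, PC1 (34% of the variance) against PC2 (15.3%), with 1 point per library. The control libraries lie between -60.9 and -40.2 on PC1 and the MCT libraries between 37.4 and 58.0, while MCT 1 lies at 77.2 on PC2.

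In MCT lungs, many transcripts of mast cells (14 of 17 list members), dividing cells (31 of 33), macrophages (19 of 23) and the extracellular matrix (21 of 30) were higher, and 9 of 20 endothelial ones were lower. None of these lists kept its camera call with an estimated correlation (adjusted p 0.341 for mast cells and 0.226 for the others). The mast cell carboxypeptidase gene Cpa3 was at 212 ± 107 FPKM (SD, n = 4) in MCT against 3.68 ± 1.23 in control. Tek, the endothelial receptor for angiopoietins, was at 21.2 ± 1.84 against 130 ± 17.7. Of 16715 genes tested with edgeR's quasi-likelihood test, 1845 were higher and 1579 lower in MCT at an adjusted p under 0.05. Among these, 618 rose and 298 fell by at least 1 on the log2 scale. The MCT and control values did not overlap for 3155 of the called genes (92.1%), against 2.86% by chance for a gene with no difference. The genes were called on these same libraries, so a high share follows from the calls and adds no support. Without MCT 2 the counts of higher and lower genes were 1191 and 975. With both control 1 and MCT 1 left out they were 1816 and 1713.

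The 10 largest rises were in Mcpt1l1, Cma1, Pimreg, Gja3, Tpsab1, Mcpt1, Cpa3, Tph1, Mcpt8l2 and Ms4a2. Of these, 7 are mast cell proteases or the mast cell IgE receptor chain Ms4a2, with log2 fold changes of 5.30 (Ms4a2) to 7.41 (Mcpt1l1). Tph1, which makes serotonin outside the brain, rose by 5.79 (SE 0.51) from 0.0475 to 2.84 FPKM. Like Tph1, Pimreg and the connexin Gja3 were near 0 in control (0.065 and 0.035 FPKM), so the fold changes of all 3 rest on few reads. That of Gja3 was 6.37, and 10.94 without control 3. The 10 largest falls were in Serpina1, Hmx3, Lrrn1, Gpihbp1, Sema3g, Sh2d7, Acer2, Lifr, Kcnk2 and Bank1. Serpina1, a serine protease inhibitor, fell by 4.07 (SE 0.33) to 1.33 ± 0.619 FPKM. Acer2, an alkaline ceramidase, fell from 204 ± 15.7 to 27.1 ± 3.62 FPKM.

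The table gives positions on Rnor_6.0. Cpa3 (ENSRNOG00000011181) lies on chromosome 2 from 105016626 to 105047984. Tek (ENSRNOG00000008587) lies on chromosome 5 from 113725717 to 113852799. Serpina1 (ENSRNOG00000032669) lies on chromosome 6 from 127610243 to 127632265, and Sema3g (ENSRNOG00000018952) on chromosome 16 from 7303578 to 7315390.

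**Figure D2:**
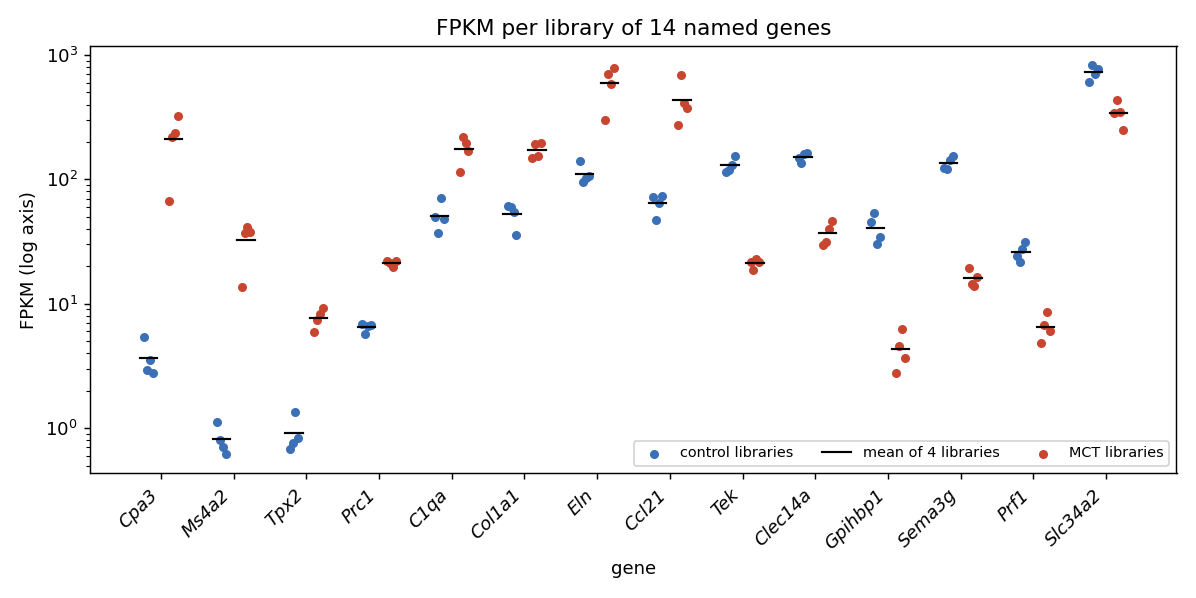
FPKM (log axis) of 14 named genes in each of the 4 control and 4 MCT libraries, with 1 point per library and a line at the mean of each group. Cpa3, Ms4a2, Tpx2, Prc1, C1qa, Col1a1, Eln and Ccl21 are higher in all MCT libraries than in any control library, and Tek, Clec14a, Gpihbp1, Sema3g, Prf1 and Slc34a2 are lower.

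Mast cell genes rose. Of 17 tested members, 14 were higher, 2 lower and 1 not past the threshold (14 and 2 adjusted over the list alone). The camera adjusted p was 3.98e-08, and the adjusted p = 0.341 with an estimated correlation. Ms4a2 was at 32.6 ± 12.7 FPKM in MCT against 0.815 ± 0.218 in control, and Fcer1a, another IgE receptor chain, rose by 4.99. The members that fell were Gata2, a transcription factor also used by endothelial cells (-1.30, SE 0.10), and the receptor Kit (-0.96). MCT 1 had a mast cell score of 4.37 against 5.81 to 6.07 in the other MCT libraries and 1.77 to 2.41 in control. The proteases Mcpt1, Mcpt1l1, Mcpt8l2, Cma1 and Tpsab1 belong to families of similar genes, so the split of reads among them is uncertain.

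Cell cycle genes rose in MCT. Of 33 tested members, 31 were higher and none lower (31 adjusted over the list alone), with a camera adjusted p of 4.13e-23 and an adjusted p = 0.226 with an estimated correlation. Tpx2, a spindle assembly factor, went from 0.91 ± 0.307 to 7.72 ± 1.39 FPKM, and Prc1, a cytokinesis factor, from 6.51 ± 0.513 to 21.2 ± 1.08 FPKM. Of 23 p53 targets, 12 were higher and none lower (13 and 3 adjusted over the list alone), with a camera adjusted p of 0.00192 and an adjusted p = 0.226 with an estimated correlation. Ccng1 rose by 1.10 (SE 0.08) and Aen, a nuclease, by 1.69 (SE 0.15). With control 1 and MCT 1 left out, 7 p53 targets were higher.

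Extracellular matrix genes rose. Of 30 tested members, 21 were higher and none lower (23 adjusted over the list alone), with a camera adjusted p of 4.7e-11 and an adjusted p = 0.226 with an estimated correlation. Eln, the elastin gene, went from 111 ± 19.5 to 594 ± 212 FPKM, and Col1a1 from 53 ± 11.9 to 173 ± 25 FPKM. In the basement membrane list, 5 of 18 members were higher and 2 lower (6 and 2 adjusted over the list alone), and its camera adjusted p was 0.197. Nid2 (1.16, SE 0.17) and Col18a1 (0.95, SE 0.13) rose, and without MCT 1 the number higher was 9. In the smooth muscle contractile list, 2 of 20 members were higher and 3 lower (2 and 3 adjusted over the list alone, camera adjusted p 0.874). Synpo2 (-0.80, SE 0.12) and Notch3 (-0.60, SE 0.09) fell. Acta2, smooth muscle actin, had a log2 fold change of 0.26 and was not past the threshold.

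Many endothelial genes fell. In the pan-endothelial list, 9 of 20 members were lower and 1 higher (9 and 2 adjusted over the list alone), with a camera adjusted p of 2.02e-05 and an adjusted p = 0.226 with an estimated correlation. Tek fell by 2.61 (SE 0.11) and Clec14a by 2.04 (SE 0.14), while the endothelial sialomucin Emcn rose by 1.15. In the capillary list, 7 of 17 members were lower and 3 higher (9 and 4 adjusted over the list alone), with a camera adjusted p of 0.0195 and an adjusted p = 0.478 with an estimated correlation. Gpihbp1, which carries lipoprotein lipase to the capillary surface, went from 41.0 ± 10.5 to 4.33 ± 1.5 FPKM, and Lyve1 from 123 ± 16.3 to 37.8 ± 5.22 FPKM. The 3 higher members were Fibin (1.09), Apln (0.98) and Kitlg (0.66), so the capillary list did not fall as a whole. Without MCT 1 the camera adjusted p of the capillary list was 0.0766.

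Genes linked to heritable pulmonary arterial hypertension fell where they changed: 9 of 22 tested members were lower and none higher (10 adjusted over the list alone). The camera adjusted p was 2.02e-05, and the adjusted p = 0.226 with an estimated correlation. Bmpr2 went from 26.7 ± 5.08 to 13.6 ± 1.07 FPKM, Acvrl1 from 285 ± 14.9 to 146 ± 20.7 FPKM and Sox17 from 61.9 ± 3.96 to 28.9 ± 4.51 FPKM. In the BMP and TGF-beta list, 8 of 33 members were lower and 5 higher (9 and 5 adjusted over the list alone, camera adjusted p 0.262). Bmpr2, Acvrl1, Eng and Smad9 were lower and stand in both lists, so the counts of lower members overlap. Smad6, an inhibitor of BMP signalling, fell by 1.27 (SE 0.14), while Tgfb2 and Tgfb3 rose by 0.47 and 0.63. The number higher was 3 without control 3 or without MCT 4. In the vasoactive list, 9 of 37 members were lower and 6 higher (9 and 7 adjusted over the list alone, camera adjusted p 0.221). The phosphodiesterase Pde3a fell by 2.15 (SE 0.20) and angiotensin-converting enzyme Ace by 1.54, while Tph1 and Adm rose. The number higher was 2 without MCT 2 and 3 without control 1, control 2 or MCT 4.

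In the epithelium, 4 of 15 alveolar type 1 members were lower and none higher (5 adjusted over the list alone), with a camera adjusted p of 0.00886 and an adjusted p = 0.47 with an estimated correlation. Lmo7 fell by 0.76 (SE 0.11) and Rtkn2 by 0.81 (SE 0.17). Of 18 alveolar type 2 members, 6 were lower and 2 higher (7 and 2 adjusted over the list alone), with a camera adjusted p of 0.0171 and an adjusted p = 0.736 with an estimated correlation. The phosphate carrier Slc34a2 went from 727 ± 91.9 to 344 ± 76.0 FPKM, and Etv5 fell by 0.87 (SE 0.11). The call of the alveolar type 2 cell list was lost without control 2, MCT 3 or MCT 4 (adjusted p 0.0737, 0.0507 and 0.0612). In the transitional list, 3 of 17 members were higher and 1 lower (3 and 1 adjusted over the list alone, camera adjusted p 0.217), with Anxa1 at 0.53 (SE 0.09) and Krt18 at -0.67 (SE 0.13). In the club cell list, 2 of 13 members were lower (2 adjusted over the list alone, camera adjusted p 0.638), the cytochrome P450 genes Cyp2b1 (-0.87, SE 0.18) and Cyp4b1 (-0.69, SE 0.16). None of 21 ciliated members was called by edgeR (camera adjusted p 0.874, 0 adjusted over the list alone), and Tppp3 had a log2 fold change of -0.39 (adjusted p 0.211).

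Macrophage and complement genes rose. Of 23 macrophage members, 19 were higher and none lower (22 adjusted over the list alone), with a camera adjusted p of 1.68e-11 and an adjusted p = 0.226 with an estimated correlation. Of 23 complement members, 15 were higher and 1 lower (15 and 1 adjusted over the list alone), with a camera adjusted p of 2.48e-05 and an adjusted p = 0.341 with an estimated correlation. C1qa went from 51.1 ± 14 to 176 ± 45.5 FPKM and C1qc from 48.0 ± 10.5 to 172 ± 48.2 FPKM, and both stand in both lists. The complement member that fell was C3 (-0.50), and no complement member was lower without control 2, control 3, control 4 or MCT 4. Of 18 MHC class II members, 8 were higher and none lower (10 adjusted over the list alone), with a camera adjusted p of 2.02e-05 and an adjusted p = 0.341 with an estimated correlation. The costimulatory ligand Cd86 rose by 1.02 (SE 0.16) and RT1-DMa by 1.01 (SE 0.10), and without MCT 2 the number higher was 5. Of 38 cytokine and chemokine members, 11 were higher and 4 lower (16 and 4 adjusted over the list alone), with a camera adjusted p of 6.64e-05 and an adjusted p = 0.226 with an estimated correlation. Ccl21, a lymphoid chemokine, went from 64.3 ± 12 to 438 ± 180 FPKM, and Cxcl12 rose by 1.51 (SE 0.18).

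Some T and NK cell genes fell. In the T and NK list, 7 of 26 members were lower and 1 higher (8 and 2 adjusted over the list alone), with a camera adjusted p of 0.0603 and an adjusted p = 0.736 with an estimated correlation. Those lower included Cd8a, Gzma and Gzmb, and Prf1, the perforin gene, went from 26.2 ± 4.11 to 6.52 ± 1.54 FPKM. Without control 2 the camera adjusted p of the T and NK cell list was 0.00738, and it was also under 0.05 without control 4, MCT 2 or MCT 3 (0.0416, 0.0447 and 0.0279), all with the preset correlation, against 0.736 with the estimated one in all libraries. The general T cell gene Cd3g rose by 0.86. In the B and plasma cell list, 1 of 21 members was higher and 1 lower (1 and 1 adjusted over the list alone, camera adjusted p 0.638), Jchain at 0.84 (SE 0.17) and Spib at -1.62 (SE 0.28). In the neutrophil list, 2 of 16 members were higher (2 adjusted over the list alone, camera adjusted p 0.127), Il1r2 (1.65, SE 0.34) and Trem1 (1.36, SE 0.30). Without control 3 or MCT 3 that p was 0.0194 or 0.0314, and over all libraries the adjusted p = 0.688 with an estimated correlation. In the interferon list, 2 of 30 members were lower and none higher (2 adjusted over the list alone), with a camera adjusted p of 0.00289 and an adjusted p = 0.736 with an estimated correlation. These were Bst2 (-0.68, SE 0.15) and Ifi44l (-1.21, SE 0.28). The number lower was 10 without MCT 3 and 1 without MCT 2, and without MCT 1 the camera adjusted p was 0.0545.

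In the oxidative phosphorylation and fatty acid oxidation list, 12 of 37 members were higher and 2 lower (18 and 3 adjusted over the list alone), with a camera adjusted p of 0.00205 and an adjusted p = 0.318 with an estimated correlation. Cycs, the cytochrome c gene, rose by 0.60 (SE 0.08), and Acadm, an enzyme of fatty acid oxidation, fell by 0.69 (SE 0.08). The number higher was 7 without control 2 or without MCT 2. In the glycolysis and hypoxia list, 4 of 31 members were higher and 2 lower (5 and 3 adjusted over the list alone, camera adjusted p 0.518). Epas1, the hypoxia-inducible factor of endothelial cells, went from 635 ± 258 (control 4 at 1011) to 164 ± 14 FPKM, and the vasodilator peptide gene Adm from 3.64 ± 0.446 to 10.3 ± 2.17 FPKM. In the circadian list, 1 of 19 members was higher and 4 lower (1 and 4 adjusted over the list alone, camera adjusted p 0.11), with the clock transcription factor gene Arntl at 1.18 (SE 0.24). The number lower was 0 without MCT 3, and 1 or 2 without MCT 2, MCT 4 or any control library. In the immediate early and glucocorticoid list, 2 of 27 members were higher and 4 lower (2 and 4 adjusted over the list alone, camera adjusted p 0.289). Zbtb16 fell by 1.56 (SE 0.26) and Klf9 by 0.84 (SE 0.15).

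None of the lists of tissue that could be carried into a lung sample passed the camera threshold. Of 20 cardiac members 1 was higher, Pln at 0.94 (SE 0.26), a call lost without any 1 of 6 libraries, and with control 1 and MCT 1 left out 4 were lower. None was called adjusted over the list alone (camera adjusted p 0.984). Of 10 adipocyte members, 2 were higher and 1 lower (2 and 1 adjusted over the list alone, camera adjusted p 0.638), with Fabp4, also a macrophage gene, at 2.43 (SE 0.33) and Lipe at -1.14 (SE 0.11). No member of the skeletal muscle, mesothelial or red blood cell lists (11, 9 and 12 tested) was called over all genes or adjusted over the list alone, with camera adjusted p of 0.794, 0.638 and 0.794. Their most abundant members were Mb (0.09, SE 0.44), Msln (0.48, SE 0.41) and Hba-a1 (-0.38, SE 0.41). The median, the mean and the camera direction of a list differed in sign for the vasoactive, club, cardiac and red blood cell lists.

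**Figure D3:**
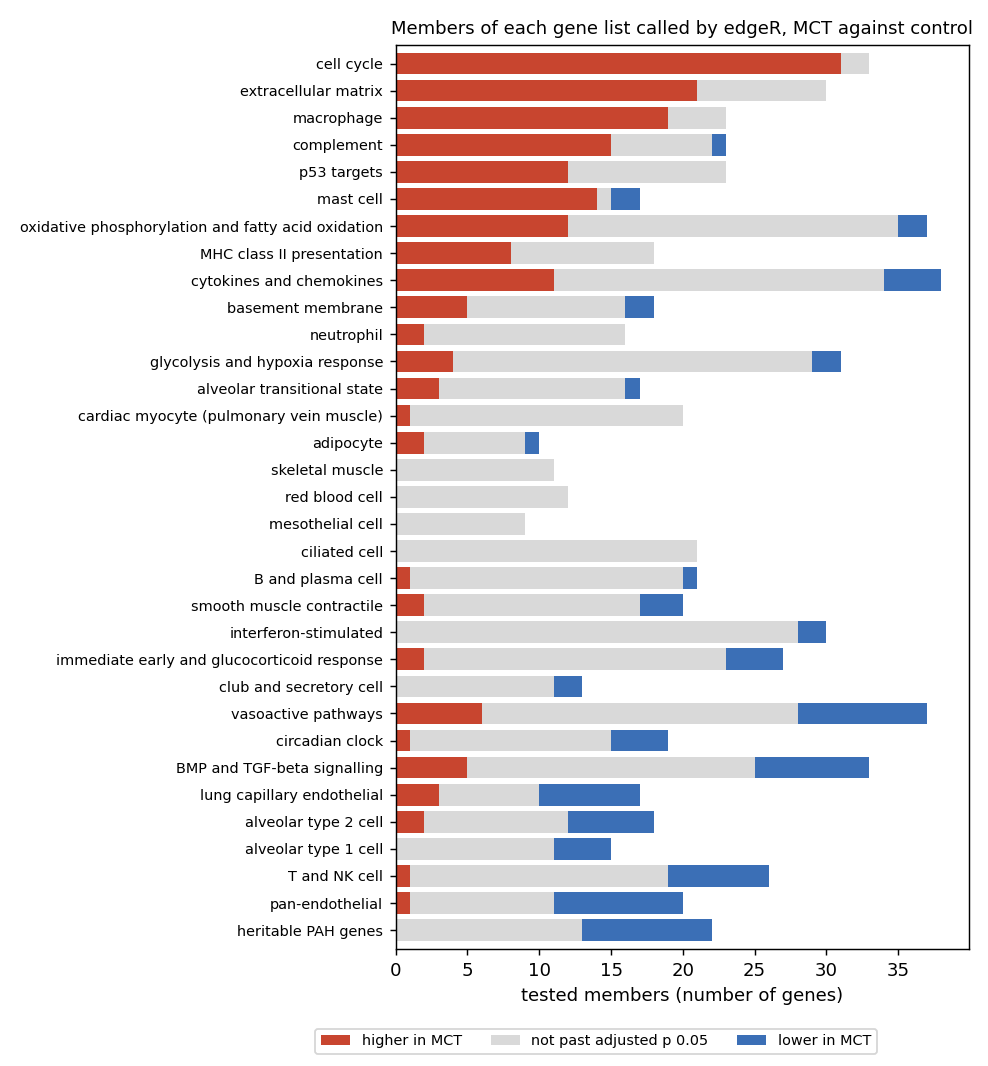
Number of tested members of each of the 33 gene lists that were higher in MCT (red), not past an adjusted p of 0.05 (grey) or lower (blue) by edgeR, ordered by the difference between higher and lower. Cell cycle, extracellular matrix and macrophage have 31, 21 and 19 members higher, and the heritable hypertension list has 9 lower.

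By camera with the preset correlation, 15 of the 33 lists passed the threshold, 9 of them upwards. None did with an estimated correlation, where the lowest adjusted p was 0.226. Of the 35 ways to split the libraries into 4 and 4, 8 gave at least 15 lists, the real one among them.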

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

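The test of mast cell genes for reads shared between paralogs, in both of its forms, was chosen only after the result was seen. The test for airway tissue with the covariate was written before its outcome was known.

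In groups of 4 libraries, 1 library lay far from the other 3 for 10 of the 166 sets examined, where chance gives about 8.3. The gap of that library to the nearest on log2 CPM, as a share of the range of the 4, was 0.987 for Bst2 (MCT 3 at 513 FPKM, the others at 321 to 328). It was 0.846 for Eln (control 1 at 140 FPKM, the others at 95.9 to 106), 0.886 for Notch3 (MCT 1 at 15.7, the others at 18.8 to 18.9) and 0.889 for Smad6 (MCT 4 at 94.3, the others at 64.5 to 65.8). For Spib it was 0.896 (control 2 at 4.94, the others at 10.2 to 10.7), and for Gja3 it was 1 (control 3 at 0.14 FPKM, the others at 0). The mitochondrial share of counts in control 4 was 3.5% against 2.86% to 2.95% in the other control libraries (0.859) and 3.24% to 4.59% in MCT.

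MCT 1 was the low library for 2 mast cell genes, Mcpt8l2 (25.1 FPKM, the other MCT libraries at 95.7 to 111, 0.909) and Ms4a2 (13.7, the others at 37.3 to 41.4, 0.92), and for the mast cell score (0.847).

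Most mast cell genes were higher in MCT. The ciliated cell score did not separate the groups (2.48 to 5 in MCT, 3.05 to 4.33 in control). It thus gave no sign of more airway tissue in the MCT libraries, but scores this spread in 4 libraries per group cannot exclude a difference. All 14 higher members kept their call with that score as a covariate. A score so alike in the groups could hardly remove calls, so the kept calls decide nothing. Reads shared between mast cell protease paralogs are argued against as the only source of the rise, since they do not reach the 11 other members and 8 of these were higher, against a median of 1 and a highest of 7 in 10000 random lists matched on expression. The median log2 fold change of the 11 was 2.34, and its 95% interval of -0.96 to 5.13 decided nothing by itself. What stays open is how the reads were split among the proteases. More mast cells, or more transcript per mast cell, may both give the pattern, and neither was tested.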

How the results depend on the processing

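The airway covariate, the removal of control 1 and MCT 1 together, read pair units and the length trend were chosen after seeing the data. The counts of 1845 higher and 1579 lower genes stayed within 1.5 times under every alternative except these: 618 and 298 with an absolute log2 fold change of at least 1, and 1191 and 975 without MCT 2. Leaving out 1 library gave 1191 to 1946 higher and 975 to 1730 lower. No called gene was called in the opposite direction under any alternative. With the replicate number as a block, 1436 were higher and 1271 lower. Deviations of libraries with the same number correlated at 0.11, 0.02, -0.02 and -0.08, and 2 of 8 libraries correlated best with their own number, so the numbers share no visible pairing. DESeq2 gave 2266 and 2181.

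Of the gene lists, 15 passed the camera threshold, 13 to 18 under the other alternatives, and 0 with an estimated correlation. There the adjusted p of those 15 was 0.226 (extracellular matrix, pan-endothelial, heritable hypertension, macrophage, cytokines, cell cycle and p53), 0.318 (oxidative phosphorylation), 0.341 (mast cell, complement, MHC class II), 0.47 (alveolar type 1), 0.478 (capillary) and 0.736 (alveolar type 2, interferon). With array weights the p was 0.0707 for the lung capillary endothelial list and 0.0988 for the interferon-stimulated list. With control 1 and MCT 1 left out it was 0.0894 for the capillary list. Lists that passed in addition were the basement membrane list with the length trend (0.00782), the T and NK cell list with no filter (0.0273), the replicate block (0.0491) or the length trend (0.0218), the neutrophil list with no filter (0.0273) and the circadian clock list with no filter (0.0482). With an estimated correlation these 4 lists had 0.736, 0.736, 0.688 and 0.341. The cause was not tested.

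Leaving out 1 library gave a range of adjusted p for each list whose call or direction changed: basement membrane 0.0103 to 0.51, smooth muscle 0.494 to 0.977, capillary 0.00456 to 0.0766, alveolar type 2 0.00189 to 0.0737, club 0.151 to 0.952, ciliated 0.0955 to 0.834, B cell 0.0894 to 0.925, T and NK 0.00738 to 0.449, neutrophil 0.0194 to 0.184, interferon 1.15e-08 to 0.0545, cardiac 0.101 to 0.977, skeletal muscle 0.524 to 0.925, mesothelial 0.0645 to 0.989, red blood cell 0.126 to 0.977 and circadian 0.0479 to 0.182.

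The number of called members moved by more than 1.5 times in some lists under other settings. Lower members were 7 for alveolar type 1 with quantile scaling against 4, 7 for interferon with the replicate block against 2, and 4 for glycolysis and hypoxia with quantile scaling or DESeq2 against 2. For circadian they were 7 with array weights or DESeq2, 2 with the length trend and 1 with the replicate block, against 4. For cardiac, 3 members were higher with the replicate block against 1, and 4 were lower with control 1 and MCT 1 left out against 0. The transitional list had 3 members lower with quantile scaling against 1, and the vasoactive and p53 lists had 3 and 7 members higher with both libraries left out against 6 and 12. The other moves under these settings were of 1 member. Leaving out 1 library also gave up to 3 T and NK members higher against 1. It gave up to 2 red blood cell members higher and up to 2 cardiac members lower, each against 0. The cause was not tested.

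Directions turned only for lists and genes that were not called in either setting. The cardiac myocyte (pulmonary vein muscle) list turned with limma at pseudocounts 0.5, 0.1 and 1 (adjusted p 0.897, 0.933, 0.849), quantile scaling (0.847), median of ratios (0.873), no filter (0.963), the FPKM filter of 1 (0.899), DESeq2 size factors (0.957), the block (0.799) and the airway covariate (0.964). The skeletal muscle list turned with limma (0.842, 0.844, 0.849), quantile scaling (0.861), array weights (0.768), median of ratios (0.861), the FPKM filter of 1 (0.618) and both libraries left out (0.806). The red blood cell list turned with quantile scaling (0.991), the FPKM filter of 1 (0.875) and the length trend (0.995), and the ciliated cell list with array weights (0.907) and both libraries left out (0.709). The log2 fold change of Mb was -0.134, -0.154 and -0.114 with limma, -0.133 with quantile scaling, -0.327 with array weights, -0.14 with median of ratios, -0.187 with the block, -0.142 with the airway covariate, -0.667 with both libraries left out, -0.034 with the length trend, and -0.595 to 0.336 leaving out 1 library. That of Hba-a1 was 0.158 with both libraries left out and -0.604 to 0.207 leaving out 1. The cause was not tested.

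Among the named genes, Ifi44l lost its call without MCT 2 (adjusted p 0.0529), and Pln lost its call without any 1 of 6 libraries (0.056 to 0.0695) and with control 1 and MCT 1 left out (0.0854). Tppp3 was called without MCT 1 (0.041) and with quantile scaling (0.0467). With limma at a pseudocount of 1, the log2 fold changes of genes with low FPKM in a group shrank by more than 1.5 times: to 1.81 for Tph1, 2.80 for Pimreg, 1.92 for Gja3, 0.825 for Il1r2, -1.68 for Lrrn1, -2.03 for Hmx3, -1.58 for Kcnk2 and -1.80 for Bank1. With the length trend that of Notch3 was -0.40. Without control 2, that of Pimreg was 8.30. The cause was not tested. Across genes, log2 fold changes correlated with gene length at a Spearman rho of -0.18, and genes are not independent replicates. In simulated data 22.5% of 1.5-fold changes were recovered. Each simulated set had 200 changed genes among 16389 to 16419 tested, while 20.5% of tested genes were called in the real data. The Benjamini-Hochberg adjustment is stricter where fewer genes change, so the 22.5% cannot tell how often small changes were missed here. The median absolute log2 fold change of the called genes was 0.634. Some small changes may still have been missed.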

Other observations

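The lists of tuft cell, lymphatic and arterial genes and the tests on them were chosen only after the leading genes had been seen, as was the test for a lower share of endothelial cells. The tests for airway tissue with the covariate, for expression level and for other splits of the libraries were written before their outcome was known.

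Many genes of tuft cells, chemosensory cells of the epithelium, were lower in MCT: of 23 tested members 14 were lower and 3 higher (camera adjusted p 1.79e-05 over these 3 lists, adjusted p = 0.144 with an estimated correlation). The taste channel Trpm5 went from 22.0 to 3.68 FPKM, the tuft cell transcription factor Pou2f3 from 3.02 to 0.498 and the cytokine Il25 from 1.73 to 0.235. Those higher were Alox5ap, Plcb2 and Ptgs1, which leukocytes or platelets also express, and 1 of them was called without control 3, MCT 2, MCT 3 or MCT 4. The lower members Krt18, Spib and Bmx and the higher member Ptgs1 also stand in other lists, Bmx in the arterial list. Some lower members are thus not specific to tuft cells either. The 6 members not past the threshold were Dclk1 (0.55, adjusted p 0.298), Rgs13, Gfi1b, Itpr3, Ltc4s and Tas1r3. All of these but Dclk1 had a negative log2 fold change.

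Arterial and Notch genes went both ways, with 9 of 15 members lower and 4 higher (camera adjusted p 0.000807, adjusted p = 0.0304 with an estimated correlation). Both values were adjusted over the 3 added lists only, not with the 33 fixed in advance. They show little by themselves, since the list was chosen after its member Sema3g was seen among the largest falls. On the log2 scale Sema3g fell by 3.07, Dll4 fell by 2.48 and Efnb2 fell by 2.10, while Cxcl12, Fbln5, Dkk2 and Gja5 rose. Without control 2 or MCT 2, 5 members were lower. Of 11 lymphatic members, 3 were higher and 2 lower (camera adjusted p 0.228): Ccl21, Mmrn1 and Prox1 rose, and Lyve1 and Ackr4 fell. Bpifa1, a secretory airway gene, was at 33.3 FPKM in MCT 1, 0.29 to 0.33 in the other MCT libraries and 0 in control.

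Of 35 splits of the libraries into 4 and 4, only the real one gave as many as 1845 higher or 1579 lower genes. The highest other gave 2. Every other split mixed MCT and control libraries, so the group difference itself widened the spread within its parts. Low counts there were likely in advance, and with 35 splits this does not exclude chance. Chance cannot be excluded for the number of lists past the threshold with the preset correlation. Of the 35 splits, 8, the real one among them, gave as many as the real 15, and the highest other gave 18. The other splits among these 8 kept most libraries of a group together. They thus carried part of the group difference and do not measure chance alone. Splits with 2 libraries of each group on each side gave up to 13 lists. Single lists were looked at after the count of 8 was known. The real split had the smallest camera p of all 35 for mast cell, pan-endothelial, cell cycle and p53. For the other 11 lists past the threshold 2 to 18 splits gave a p as small, 18 for interferon.

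Many endothelial genes were lower in MCT: 9 of 20 pan-endothelial members, with Emcn higher. More airway tissue in the MCT libraries, as scored by ciliated genes, was not seen, as the scores overlapped (2.48 to 5 in MCT, 3.05 to 4.33 in control). With such a spread in 4 libraries per group, a difference cannot be excluded. All 9 lower pan-endothelial members kept their call with that score as a covariate. This decides nothing, since a score so alike in the groups could hardly remove calls. A lower share of endothelial cells in the MCT libraries would lower the members alike only if these cells were their sole source and were lost evenly. The 95% interval of 5 of 20 members lay above the list median of -0.50, and that of 6 below it. Chance gives 0.5 above if all members share the same fold change. The members thus did not fall alike, but this cannot decide on a lower share, since those conditions were not tested. A changed state or mix of endothelial cells may add to such a loss and was not tested.

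Many tuft cell genes were lower in MCT. Less airway tissue in the MCT libraries, as scored by ciliated genes, was not seen, as the scores overlapped (2.48 to 5 in MCT, 3.05 to 4.33 in control). Ciliated members had a median log2 fold change of 0.31, against -1.43 for tuft cell members. A smaller difference in airway tissue cannot be excluded with such a spread in 4 libraries per group. With that score as a covariate 14 of 14 lower members kept their call. The kept calls decide nothing, since a score so alike in the groups could hardly remove them. The list median of -1.43 lay at percentile 0 of 10000 random lists matched on mean expression, which shows little by itself, since the list was chosen after one of its genes, Sh2d7, was seen among the largest falls. A trend of genes at this expression level is argued against by the random lists themselves, whose medians lay between -0.19 and 0.23 in their central 95%. As a hypothesis, MCT lungs may hold fewer tuft cells or less transcript per cell, and these were not told apart by any test.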
